A study of Mus musculus with 8 samples.

How the data were processed

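Total RNA of sorted Sca1+Lin- cells (positive for the surface marker Sca1, negative for lineage markers) from mouse bone marrow was amplified and hybridised to 1-colour Affymetrix arrays, 3 from wild-type and 5 from Sca1-MALT1 transgenic mice. The deposited table held 1 log2 value per probe set and array, made by the authors with RMA (robust multi-array average, which corrects the background, normalizes the arrays by quantiles and summarises the probes of a set), per the submitters' processing notes. The RMA version, the software, the probe set definitions and the set of arrays normalized together are not given in the sources used here. The log2 scale was read from the deposited values, which ran from 2.73 to 15.41 with array medians of 6.40 to 6.48. The deposited values were used as they stood, with no further normalization and no filter on dim probe sets. RMA gives no detection call, so a low signal was not treated as absence of the transcript. Where 1 group's mean lies below the array medians, the printed difference is that of the deposited values and not against a signal shown to exceed background.

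The table held 45101 probe sets, of which 64 were control probe sets and were left out of all gene tests. In the platform annotation used here, 34945 probe sets had 1 gene symbol, 932 had several, and 9160 were not listed and stayed unnamed. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, which served for names only and gave no coordinates. For each gene the probe set with the highest mean over all 8 arrays was taken, which gave 18193 genes, 18031 of them named through an identifier match. Sca1 itself (gene Ly6a) had no probe set with a single listed gene and was not analysed here.

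Sca1-MALT1 was compared with wild type over all 8 arrays with limma 3.58.1 (lmFit and eBayes at default settings) in R 4.3.3, with genotype as the only term. Adjusted p-values are Benjamini-Hochberg values over all 18193 genes, two-sided, with a threshold of 0.05 and no minimum fold change. All log2 differences are Sca1-MALT1 minus wild type, with the standard error (SE) of the limma fit; group values are mean ± SD. Measures of single values were compared by an exact two-sided permutation test over the 56 ways to split 8 arrays into 3 and 5, whose smallest possible p is 0.0179. The number of arrays limits the precision. In data simulated for this comparison over 18193 genes, noise was independent between genes and 200 genes were changed per round, which gave 903 calls in 5 rounds. There the fit found 57.6% of genes changed by 1 log2 unit, 87.6% of those changed by 2 and 96.8% of those changed by 3. Of its calls, 5.43% were false. The real comparison called 16 genes, and the adjusted threshold is stricter with fewer changed genes, so these shares may be too high for it.

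The 35 gene lists, the tests, the rule for naming genes and all but the added alternatives were fixed before the data were examined. The lists held 805 entries, 725 of them measured. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 35 lists, then with camera at an estimated correlation and with fry. Counts of list members past the threshold are given over all genes and adjusted over the list alone. The exact permutation test on the mean signal of each list was added after the data were seen. Named genes were Malt1, Bcl10 and Birc3, the 12 genes per direction with the largest difference among those past the threshold whose groups did not overlap (places left over went to the genes with the lowest unadjusted p and no overlap, said not to have passed), and up to 4 members per list with the lowest unadjusted p. Other list members are named where the text says so. Array similarity was measured as 1 minus Pearson's r over all genes, and RNA quality as the 3' minus 5' log2 signal of the Gapdh and beta-actin control probe sets.

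The alternatives fixed beforehand were quantile normalization, centring on the array median, both filters on dim genes, all probe sets, the mean of a gene's probe sets, an intensity trend with robust variance, array quality weights, stricter thresholds, the replicate number as a block, and leaving out each array in turn. A term for sex read from Xist (arrays with a log2 Xist signal above 9 against the rest), the Xist-low arrays alone, and the fit without 21 immunoglobulin and J chain genes were added after the data were seen. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical. The labels give no age, sex, batch or array date.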

Results

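Gene expression was measured in Sca1+Lin- bone marrow cells, a fraction enriched for haematopoietic stem and progenitor cells, from 3 wild-type samples and 5 samples of Sca1-MALT1 transgenic mice. The transgene is named for the Sca1 promoter and for MALT1, a protease and scaffold of antigen receptor signalling to NF-kB and an oncogene of MALT lymphoma. The comparison asks how the expression profile of this fraction differs between the genotypes. Genes of mature cells also read high in wild type, with means of 14.74 for S100a8, 14.58 for Ighm and 12.55 for Ms4a1, against 10.11 for Kit. Probe sets of different genes are not on a common scale, so these values do not measure the share of mature cells. The sorted cells may not be progenitors alone, which was not tested. Arrays correlated with one another at r between 0.956 and 0.983 over 18193 genes.

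The 3 largest falls among genes past the threshold were in early lymphoid and B cell genes, and Jchain, a gene of plasma cells, rose in Sca1-MALT1. The recombinase gene Rag1 fell by 5.88 on the log2 scale (SE 0.52, adjusted p = 0.00596), to 5.05 ± 0.77 (n = 5). The surrogate light chain gene Vpreb1 fell by 5.55 (SE 0.48, adjusted p = 0.00596), to 5.78 ± 0.82 (n = 5). Both means lie below the array medians of 6.40 to 6.48, where signal over background could not be judged, so no fold is given. Jchain, which joins the chains of secreted IgM and IgA, rose by 2.58 (SE 0.27, 5.99-fold higher, adjusted p = 0.0163). Of 18193 genes, 16 passed the threshold in limma's test, 8 higher and 8 lower in Sca1-MALT1, and 1852 had an unadjusted p under 0.05 by limma's test. In 1298 genes, 7.13% of those tested, the groups did not overlap, 776 higher and 522 lower, where chance gives 3.57%.

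The Malt1 transcript itself did not pass the test. Its brightest probe set read 9.34 ± 0.38 (SD, n = 3) in wild-type and 9.83 ± 0.31 (n = 5) in Sca1-MALT1 cells, a log2 difference of 0.49 (SE 0.22, adjusted p = 0.507, exact permutation p = 0.107). The other two probe sets differed by 0.24 (exact permutation p = 0.661) and 0.17 (exact permutation p = 0.911). The probe sets were made for the mouse transcript, and the labels do not say which species or which part of the gene the transgene carries, so these values check the labels neither way. Bcl10, the partner of MALT1, differed by 0.14 (SE 0.21, adjusted p = 0.863), and Birc3, whose human counterpart is fused to MALT1 in MALT lymphoma, by 0.18 (SE 0.21, adjusted p = 0.822). Probe sets disagreed in sign for both genes.

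The 8 genes that fell were led by early lymphoid and B cell genes. The surrogate light chain gene Igll1 dropped from 10.83 ± 0.54 (n = 3) to 6.92 ± 0.24 (n = 5), a log2 difference of -3.92 (SE 0.24, adjusted p = 0.00228), while its dimmer probe set differed by 0.22. Niban3, which is expressed in B cells, fell by 3.18 (SE 0.29, adjusted p = 0.00618), and the second recombinase gene, Rag2, fell by 2.46 (SE 0.30, adjusted p = 0.0374). Cnn3, an actin-binding calponin, fell by 1.80 (SE 0.15, adjusted p = 0.00596) with the same sign in all 6 of its probe sets. Cyb561a3, a lysosomal cytochrome, and Slc37a2, a sugar phosphate exchanger, fell by 1.01 (SE 0.12, adjusted p = 0.0374) and 0.92 (SE 0.12, adjusted p = 0.0483). The 4 remaining places were taken by genes that did not pass, Tmem108 at -1.11, Capsl at -2.06, Wdfy4 at -1.27 and Ddx4, a germ cell RNA helicase, at -4.01, with adjusted p-values of 0.059 to 0.0816. The probe sets of Wdfy4 disagreed in sign.

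Jchain was 1 of the 8 genes that rose. The kappa variable gene Igkv8-30 rose by 2.85 (SE 0.21, adjusted p = 0.00317), to 14.47 ± 0.16 (n = 5). Mt2, a metallothionein that binds zinc and copper, rose by 2.89 (SE 0.25, adjusted p = 0.00596), and Sec24a, a coat protein of vesicles that leave the endoplasmic reticulum, rose by 1.39 (SE 0.15, adjusted p = 0.0189). The MAP kinase gene Mapk12 rose by 1.71 (SE 0.11, adjusted p = 0.00228), and Rasgrp3, a Ras exchange factor of B cell receptor signalling, rose by 2.12 (SE 0.25, adjusted p = 0.0362). Oosp1, first known from oocytes, and Cacna1s, a calcium channel subunit of muscle, rose by 3.65 (SE 0.44, adjusted p = 0.0362) and 2.79 (SE 0.36, adjusted p = 0.0477). Genes that did not pass but filled the places left were Mt1 at 3.07, Igk at 5.47 with 1 of its 4 probe sets near 0, Efemp1 at 1.60 and Tmem176a at 1.12, with adjusted p-values of 0.0583 to 0.059.

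**Figure D1:**
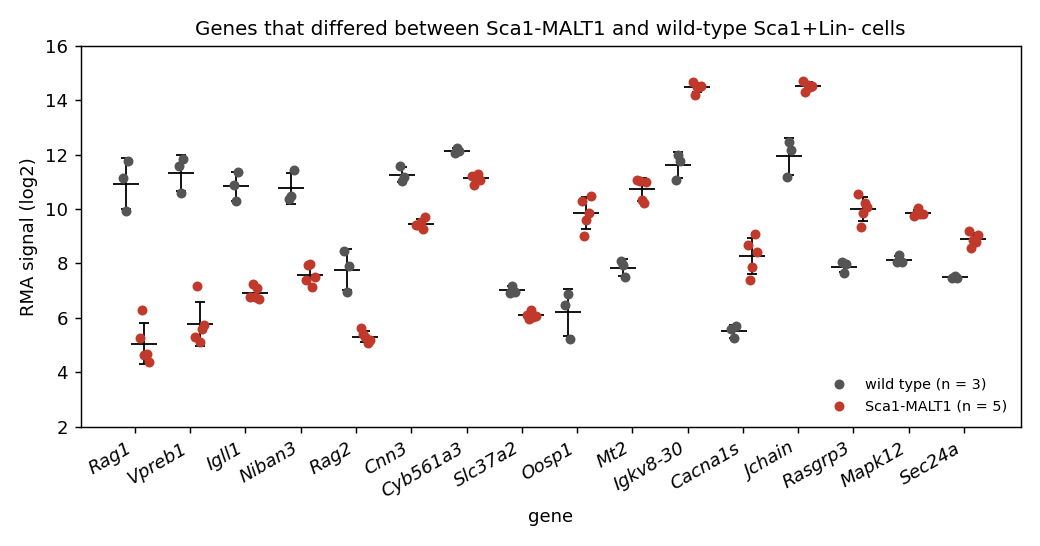
RMA signal (log2) of the 16 genes that passed the threshold, 8 lower on the left and 8 higher on the right. Each point is 1 array (grey, wild type, n = 3; red, Sca1-MALT1, n = 5), and bars show mean ± SD; for every gene all Sca1-MALT1 arrays lie on one side of all wild-type arrays.

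With each array left out in turn, 8 of the 16 genes passed in all 8 fits: Rag1, Vpreb1, Igll1, Niban3, Cnn3, Mt2, Igkv8-30 and Mapk12. The other 8 each lost the call in at least 4 fits, with adjusted p-values up to 0.179 (Cacna1s without wild-type replicate 2). Jchain lost it in 4, without wild-type replicate 3 and without Sca1-MALT1 replicates 1, 3 and 5 (adjusted p up to 0.0718). The number of genes past the threshold was 10, 8 and 9 without Sca1-MALT1 replicates 1, 3 and 5, and 38 without replicate 2.

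The plasma cell list had the largest median difference of the 16 lists that passed. All 17 measured genes were higher in Sca1-MALT1, with a median log2 difference of 1.74 (camera adjusted p = 2.22e-20; adjusted p = 0.358 with an estimated correlation; fry adjusted p = 0.0383). The mean signal of the list was higher in all 5 Sca1-MALT1 arrays than in all wild-type arrays (exact permutation p = 0.0179, the smallest possible). Jchain alone passed over all genes, and 16 genes passed adjusted over the list alone. Xbp1, the transcription factor of the secretory programme, differed by 1.32 (SE 0.22, adjusted p = 0.109), and Edem1, which sorts misfolded glycoproteins for degradation, by 2.82 (SE 0.47, adjusted p = 0.109). Igha, the constant chain of IgA, read 9.35 ± 2.76 (n = 3) in wild-type and 15.28 ± 0.11 (n = 5) in Sca1-MALT1 cells (adjusted p = 0.109), the latter close to the highest value of any array, 15.41. Further members, named beyond the rule, were Prdm1, the regulator of plasma cell fate, at 2.76, Tnfrsf17, a survival receptor of plasma cells, at 3.37, and the surface marker Sdc1 at 2.13, none past the threshold over all genes.

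Genes of the unfolded protein response, which shares 4 genes with the plasma cell list, were higher as a group. All 22 measured genes were higher, with a median of 0.65 (camera adjusted p = 1.19e-09; adjusted p = 0.358 with an estimated correlation; exact permutation p = 0.0357 for the mean signal). No gene passed over all genes and 8 passed adjusted over the list alone. The chaperone gene Dnajb9 differed by 1.35 (SE 0.21, adjusted p = 0.0915) and Creld2 by 1.53 (SE 0.38, adjusted p = 0.271).

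The B cell list was lower as a group, with 18 of 22 measured genes lower and a median of -1.04 (camera adjusted p = 1.65e-07; adjusted p = 0.358 with an estimated correlation; exact permutation p = 0.0179 for the mean signal). Igll1 and Vpreb1 fell, and 20 genes did not pass over all genes; adjusted over the list alone, 7 were lower and 2 higher. Spib, an ETS factor of B cells, differed by -2.21 (SE 0.43, adjusted p = 0.180), and Pax5, the commitment factor of the lineage, by -1.16 (SE 0.24, adjusted p = 0.204). The 2 higher genes, named beyond the rule, were Ighm, the heavy chain of IgM, at 0.76 (adjusted p = 0.219) and Pou2af1, a coactivator of immunoglobulin genes, at 1.18 (adjusted p = 0.383), both of which plasma cells also express. Ighm averaged 15.34 in Sca1-MALT1, close to the highest value of any array, 15.41. The lymphoid priming list was lower too, with a median of -0.38 and a mean of -0.95, 11 of 17 genes being lower (camera adjusted p = 8.47e-05; adjusted p = 0.358 with an estimated correlation; exact permutation p = 0.0179 for the mean signal). Rag1 and Rag2 fell, 15 genes did not pass, and 6 passed adjusted over the list alone, all lower. Il12a differed by -1.59 (SE 0.29, adjusted p = 0.128), the E protein gene Tcf3 by -0.78 (SE 0.18, adjusted p = 0.224), and Dntt, the terminal transferase of early lymphocytes, by -3.71 (SE 0.98, adjusted p = 0.295, named beyond the rule). The germinal centre B cell list did not pass (median 0.05, 8 genes, camera adjusted p = 0.451), with Mef2b at 0.62, S1pr2 at 0.37, Fas at 0.50 and Mybl1 at -0.13.

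Lists of stem cells and myeloid cells were lower as groups by camera, and none of their genes passed. The stem and multipotent progenitor list had a median of -0.46 with 20 of 26 genes lower (camera adjusted p = 0.0188; adjusted p = 0.714 with an estimated correlation; exact permutation p = 0.375 for the mean signal), with Cd34 at -2.15, Hoxa9 at -1.82, Hlf at -1.33 and Gfi1b at 0.91. Its mean was lower than in all wild-type arrays in 3 Sca1-MALT1 arrays, while Sca1-MALT1 replicate 5 had the highest mean of all 8 arrays, 9.90. The list did not pass without wild-type replicates 1 or 2 or Sca1-MALT1 replicates 1 or 4 (adjusted p up to 0.344). The neutrophil and granule list had a median of -0.84 with 14 of 18 genes lower (camera adjusted p = 0.0188; adjusted p = 0.714 with an estimated correlation; exact permutation p = 0.589 for the mean signal), with S100a9 at -1.30, S100a8 at -0.81, Csf3r at -1.27 and Ltf at -1.19. Sca1-MALT1 replicate 4 had the highest mean of all 8 arrays, 13.19, against 10.87 to 11.86 in wild type. The list did not pass without wild-type replicate 3 or Sca1-MALT1 replicates 3 or 5 (up to 0.211). The monocyte, macrophage and dendritic cell list had a median of -0.48 with 18 of 23 genes lower (camera adjusted p = 0.0267; adjusted p = 0.714 with an estimated correlation; exact permutation p = 0.357 for the mean signal), with Csf1r at -1.69, Lyz2 at -1.33, Itgax at -0.62 and Ctss at 0.52. Here too replicate 4 had the highest mean, 9.44, against 8.29 to 9.41 in wild type. The list did not pass without wild-type replicate 3 or Sca1-MALT1 replicates 2, 3 or 5 (up to 0.469). The plasmacytoid dendritic cell list did not pass (median -0.25, 14 genes, camera adjusted p = 0.307), with Tlr7 at -0.77, Pacsin1 at 0.62, Siglech at -0.35 and Tex2 at 0.32.

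T cell and NK cell lists were higher by camera. Their means were above all wild-type arrays in 4 of 5 Sca1-MALT1 arrays and below all of them in replicate 4 (T cell 8.16 against 8.33 to 8.64, NK cell 7.74 against 8.20 to 8.29). In the T cell list, 18 of 19 genes were higher, with a median of 0.59 (camera adjusted p = 5.97e-05; adjusted p = 0.714 with an estimated correlation; exact permutation p = 0.143 for the mean signal). None passed over all genes and 2 passed adjusted over the list alone, the kinase gene Zap70 at 0.80 (SE 0.17, adjusted p = 0.209) and the costimulatory receptor Cd28 at 1.69 (SE 0.45, adjusted p = 0.295); Thy1 stood at 1.43 and Cd6 at 0.93. In the NK cell list 9 of 14 genes were higher and 5 lower, with a median of 0.9998 and a mean of 0.55 (camera adjusted p = 0.0149; adjusted p = 0.714 with an estimated correlation; exact permutation p = 0.286 for the mean signal), and 7 genes passed adjusted over the list alone, 6 higher and 1 lower. The chemokine gene Ccl5 stood at 1.93, Nkg7 at 1.17 and Fasl at 2.26, against -2.76 for the granzyme gene Gzma. This list did not pass without Sca1-MALT1 replicate 2 (adjusted p = 0.135). The group 2 innate lymphoid list did not pass (9 genes, camera adjusted p = 0.902), with a median of -0.15, a mean of 0.14, Il2ra at 1.19, Gata3 at 0.77, Hes1 at -0.23 and Il5 at -0.16.

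Erythroid and stromal lists were higher and the endothelial list was lower by camera, with none of their genes past the threshold over all genes. The erythroid list had a median of 0.50, with 15 of 18 genes higher (camera adjusted p = 0.00139; adjusted p = 0.714 with an estimated correlation; exact permutation p = 0.25 for the mean signal), 1 of them past the threshold adjusted over the list alone. Its mean was below all wild-type arrays in Sca1-MALT1 replicate 2, 9.81 against 9.83 to 10.22. Car1, a carbonic anhydrase of red cell precursors, differed by 2.45 (SE 0.45, adjusted p = 0.134), Gata1 by 0.94, Rhag by 1.03 and Epor by 0.63. The stromal and bone lineage list had a median of 0.45 with 15 of 18 genes higher (camera adjusted p = 0.0111; adjusted p = 0.714 with an estimated correlation; exact permutation p = 0.179 for the mean signal), with 5 higher and 1 lower adjusted over the list alone. Igfbp5 stood at 2.32 and Dcn at 1.33, each with a probe set of opposite sign, Col5a1 at 0.86 and Postn at -1.73; the list did not pass without wild-type replicates 2 or 3 (adjusted p up to 0.115). The endothelial list had a median of -0.61 with 15 of 18 genes lower (camera adjusted p = 4.36e-07; adjusted p = 0.358 with an estimated correlation; exact permutation p = 0.0536 for the mean signal), and 3 were lower adjusted over the list alone. Plvap stood at -1.69, Emcn at -1.19, Kdr at -0.89 and Eng at -0.55. Megakaryocyte and platelet genes (17 genes, median -0.01, mean 0.07, camera adjusted p = 0.969) and mast cell, basophil and eosinophil genes (14 genes, median 0.00015, camera adjusted p = 0.902) did not pass. Among them Rab27b stood at 1.51, Selp at 0.88, Prg2 at 2.67, Gzmb at 1.05 and Hdc at -1.68.

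Targets of NF-kB, the pathway that MALT1 activates, did not pass as a list. Their median was 0.14 over 41 genes (camera adjusted p = 0.162), and 1 gene passed adjusted over the list alone. Of the members with the lowest p, Ccl5 stood at 1.93, the feedback inhibitor Tnfaip3 at 1.32 (SE 0.37, adjusted p = 0.318), Junb at 1.29 and Ebi3 at -1.79. MALT1 complex and NF-kB pathway genes did not pass either (27 genes, median 0.13, camera adjusted p = 0.244), with Rela at 0.44, Birc2 at 0.43 and Syk at -1.16, whose probe sets disagreed in sign. Regnase-1 and Roquin, which MALT1 cleaves, and the transcripts they destabilise had a median of 0.10 over 17 genes (camera adjusted p = 0.0949), with Ctla4 at 1.55, Zc3h12d at 1.35, Cd274 at 0.61 and Nfkbiz at 0.80. Chemokine and lymphoid homing genes did not pass (15 genes, median 0.08, camera adjusted p = 0.317), with Cxcr3 at 1.58, Cxcl12 at 2.35, Itgal at 0.46 and Cxcr5 at -0.997.

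Interferon-induced genes were lower by camera, with a median of -0.22, 23 of 30 genes being lower (adjusted p = 0.0267; adjusted p = 0.714 with an estimated correlation; exact permutation p = 0.321 for the mean signal) and with Ifi27l2a at -1.64, Oas2 at -1.14, Oasl1 at -0.72 and Zbp1 at 0.71. Sca1-MALT1 replicate 2 had the highest mean of all 8 arrays, 10.17. The list did not pass without wild-type replicate 1 or Sca1-MALT1 replicates 1, 3 or 5 (up to 0.306). Immediate early and heat shock genes were higher by camera, with a median of 0.38, 20 of 29 genes being higher (adjusted p = 0.00306; adjusted p = 0.358 with an estimated correlation; exact permutation p = 0.0714 for the mean signal), led by Fosb at 2.18, Fos at 1.60 and Jun at 1.58, none past the threshold over all genes or adjusted over the list alone. MHC class II genes (10 genes, median -0.003, camera adjusted p = 0.798) and MHC class I genes (12 genes, median 0.27, camera adjusted p = 0.115) did not pass, with Cd74 at 0.82, H2-Eb2 at 0.99, H2-Ob at -1.24, B2m at 0.27 and Nlrc5 at 0.67.

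S phase genes were lower by camera, with 23 of 27 genes lower and a median of -0.23 (adjusted p = 0.0471; adjusted p = 0.714 with an estimated correlation; exact permutation p = 0.411 for the mean signal), including Uhrf1 at -1.03, Rfc4 at -0.58 and Prim1 at -0.48, against Ccne1 at 0.53. The list did not pass without wild-type replicate 1 or Sca1-MALT1 replicates 1, 3 or 5 (up to 0.699). Oxidative phosphorylation genes were lower by a small amount, with a median of -0.14, 28 of 41 genes being lower (camera adjusted p = 0.0187; adjusted p = 0.714 with an estimated correlation; exact permutation p = 0.286 for the mean signal) and with Ndufa5 at -0.64, Ndufb3 at -0.56 and Cox6a1 at -0.55. They did not pass without wild-type replicates 1 or 2 or Sca1-MALT1 replicate 3 (up to 0.469). G2 and M phase genes (30 genes, median 0.06, camera adjusted p = 0.851) and glycolysis genes (17 genes, median 0.003, camera adjusted p = 0.481) did not pass, nor did MYC target and ribosome biogenesis genes (32 genes, median -0.14, camera adjusted p = 0.0973) or cytosolic ribosomal protein genes (29 genes, median -0.06, camera adjusted p = 0.141). Top2a stood at -0.33, Pfkp at 0.61, Nop56 at -0.65 and Rpl14 at -0.83. Also not past the threshold were p53 target genes (21 genes, median 0.20, camera adjusted p = 0.297), BCL2 family genes (14 genes, median -0.12, mean 0.04, camera adjusted p = 0.579) and polycomb and chromatin regulators (26 genes, median -0.10, camera adjusted p = 0.123). Bok stood at -0.59, Trp53inp1 at 0.62, Smarca4 at -0.86 and Ezh2 at -0.97, the latter 2 past the threshold adjusted over the list alone.

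**Figure D2:**
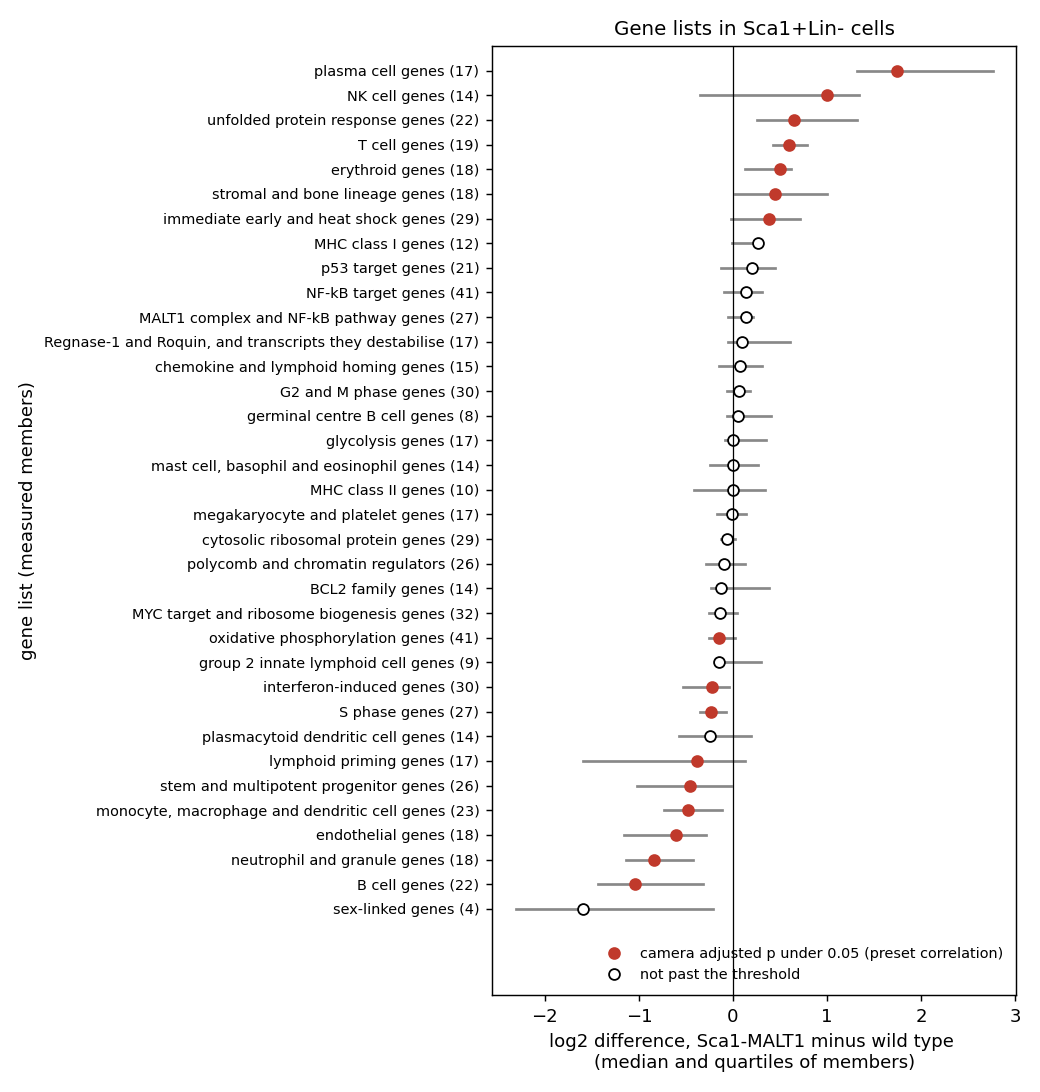
Median log2 difference (Sca1-MALT1 minus wild type) of the measured genes of each of 35 lists, with lines from the lower to the upper quartile and the number of genes in brackets. Filled red points passed camera's adjusted threshold of 0.05 at the preset correlation; the plasma cell list has the highest median, 1.74, and none of the lists passed with an estimated correlation.

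Of the 35 lists, 16 passed by camera, 7 higher and 9 lower, against 0 with an estimated correlation. By fry, which here tested for a shift in 1 direction, 1 passed, the plasma cell list. Fry's test for changes in mixed directions passed 8 lists, among them the B cell (adjusted p = 2.31e-05) and lymphoid priming (0.000164) lists. It also passed the plasmacytoid dendritic cell (0.00762) and polycomb (0.0184) lists, which did not pass by camera. With each array left out in turn, 8 lists passed in all 8 fits: plasma cell, unfolded protein response, B cell, lymphoid priming, endothelial, T cell, erythroid, and immediate early and heat shock genes. Camera at the preset correlation also called 4 to 18 lists in the other splits of the 8 arrays. Passing in all 8 fits therefore does not show that a list follows genotype.

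Sex-linked genes split the Sca1-MALT1 arrays. Xist, which only cells with an inactive X chromosome express, read 13.09 and 12.46 in Sca1-MALT1 replicates 2 and 4 and 6.20 to 6.58 in the other 6 arrays, and the Y-linked gene Eif2s3y read 3.75 and 3.56 there, against 10.65 to 11.43. The list did not pass (4 genes, median -1.59, camera adjusted p = 0.397), with Kdm5d at -2.05 and Uty at -1.14. Over the 6 Xist-low arrays, 59 genes passed the threshold, including 14 of the 16.

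On average, arrays of the same genotype correlated more closely than arrays of different genotypes, but Sca1-MALT1 replicates 2 and 4, the 2 arrays with high Xist, did not. Their mean r was 0.974 and 0.964 with their own group and 0.975 and 0.966 with wild type. The mean distance, 1 minus r, was 0.0333 between and 0.0273 within genotypes, a difference of 0.00598 (exact permutation p = 0.0357). With any single array but Sca1-MALT1 replicate 4 left out, the exact permutation p was between 0.0571 and 0.286. Fewer splits remain with an array left out, so the smallest possible p is higher there. The mean distance within Sca1-MALT1 was 0.0289 and within wild type 0.0220 (exact permutation p = 0.304). The 3' minus 5' signal of the control genes, which grows as RNA or its copies get shorter, was 2.28 ± 0.13 (n = 3) in wild type and 2.14 ± 0.41 (n = 5) in Sca1-MALT1 (exact permutation p = 0.661). Without Sca1-MALT1 replicate 5, which read 2.85, the difference was -0.32 (exact permutation p = 0.0286, the smallest possible without that array). The other Sca1-MALT1 arrays read 1.75 to 2.04, all below the 2.19 to 2.42 of wild type. Whether this measure bears on the differences between genotypes was not tested.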

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

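The tests of shared immunoglobulin sequence, of a stress response, of the share of plasma cells, of dilution and of RNA length, the splits for the lowest list, and the fit on the Xist-low arrays were chosen after the results were seen. In the 5 Sca1-MALT1 arrays, 13 of 197 measures had 1 array far from the other 4 by Dixon's criterion. Chance gives about 1 in 20 such groups, or 9.85 of 197.

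In replicate 4 the mean log2 signal of the T cell list was lowest, at 8.16, against 9.15 to 9.45 in the other 4 arrays, and with it Cd28 (8.61), Thy1 (10.99) and Cd6 (7.15). In the same array Pacsin1 was lowest (7.01) and the mitotic checkpoint gene Bub1b highest (11.09). In replicate 2 Gzmb (9.48) and Polk (8.99) were highest, and the mean of immediate early and heat shock genes was lowest (9.27). In replicate 3 Mapk12 was highest (10.05) and Ndufb3 lowest (10.68). In replicate 5 the mean of megakaryocyte and platelet genes was highest (8.64), as was the 3' minus 5' signal of the control genes (2.85). Among probe sets without a single named gene, which the gene tests left out, 8 passed the threshold when all probe sets were fitted, 7 higher and 1 lower. Of these, 6 were annotated with several genes and 2 were not listed. Among the 6, those higher carried immunoglobulin kappa genes, and the 1 lower, at -1.93, carried Vpreb2 and Vpreb1. The largest difference, 8.16, was in a probe set that was not listed.

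The 16 genes past the threshold exceeded the highest count of any other split of the 8 arrays, 2, and the real split was the only 1 of 56 as large. This is the smallest share the design can give, so chance is unlikely for the count of genes but not excluded. The 16 gene lists did not exceed the highest other count, 18, and 8 of 56 splits gave as many, so chance cannot be excluded for the count of lists. The plasma cell list had the lowest camera p of the 35 lists, 6.34e-22. For this list itself the real split was the only 1 of 56 as low, with 6.94e-15 for the lowest other split, but the list was picked as the lowest of 35. In 7 of 56 splits, the real one included, the lowest p of any list was as low, with 7.11e-48 for the lowest other split, so chance cannot be excluded for a lowest p of this size.

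Plasma cell genes were higher in Sca1-MALT1, and 14 of the 17 measured also read above the median gene in wild-type cells. Immunoglobulin probe sets that share sequence were argued against as the whole cause, since the 15 members that are no immunoglobulin or J chain genes had a median log2 difference of 1.57 with 11 of them higher without overlap, and so was sex, since the median over the 6 Xist-low arrays was 1.999. A stress response of the endoplasmic reticulum alone was argued against, since plasma cell genes outside the response list exceeded response genes outside the plasma cell list by 1.33 in the median (permutation p = 0.00012 across genes, which are not independent). A larger share of plasma cells among the sorted cells and more secretory expression per cell cannot be told apart, since either would raise these genes, and the 9 of 13 plasma cell genes outside the response list that were higher without overlap restate the pattern. The lineage antibodies of the sort (not listed in the labels) and the age of the mice (not given) stay open as untested.

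Genes of early lymphoid and B cell progenitors were lower in Sca1-MALT1, with a median of -3.92 over Rag1, Rag2, Igll1, Vpreb1 and Dntt, genes picked after their values were seen. Sex was argued against, since their median over the 6 Xist-low arrays was -4.27. Dilution by RNA of plasma cells alone would lower the genes of other cell types alike. It was tested in 3 forms, each chosen after the one before had been seen. Only the last argues against it without picked genes, and only for the B cell list. That list holds Igll1 and Vpreb1 but not Rag1, Rag2 or Dntt. The first set the median of the 5 picked genes, -3.92, against the stem and multipotent progenitor median, -0.46, which excludes nothing since the genes were picked for their falls. The second, the B cell list median less the stem and multipotent progenitor median, gave -0.59 (permutation p = 0.111 across genes) and did not decide. In the third, the mean signal of the fixed B cell list, less the mean over 8 lists of other cell types, differed by -1.12 and was lower in all 5 Sca1-MALT1 arrays than in all wild-type arrays (exact permutation p = 0.0357). Set against 1 list at a time, the p was 0.0179 for T cell and stromal genes, 0.0357 for NK cell and erythroid genes, 0.5 for stem and multipotent progenitor genes, 0.375 for endothelial and for monocyte genes and 0.696 for neutrophil genes. The genotypes separated only against the lists that rose, and overlapped against those that were lower. With 3 forms tried, the p of 0.0357 is not corrected for that choice, and dilution together with a gain of the other cells that rose stays open. Fewer early lymphoid or B cell progenitors in the sorted fraction may account for the difference, as may lower expression in each of them or a difference in age. These were not tested.

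Sca1-MALT1 replicate 5 had the lowest 5' signal relative to the 3' signal. The gap was wider there than in each of the other 7 arrays in 2 of 2 control genes, 3.20 against at most 2.92 for Gapdh and 2.49 against at most 2.14 for beta-actin. The 3' signal of beta-actin was itself lower there, 12.97 against 14.51 to 14.92. Shorter RNA in this array and other causes cannot be told apart, since these 2 genes are the ones that define the pattern. The array did not decide most gene list calls, since 12 of 16 lists were called in the same direction without it. No biological explanation was tested.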

How the results depend on the processing

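The fits with sex read from Xist as a term, on the Xist-low arrays alone and without immunoglobulin genes were chosen after the data were seen. All 16 genes kept their sign in each alternative fit with 1 value per gene that tested them. Over all probe sets, the dimmer probe set of Igll1 went the other way, at 0.22. The count of genes past the threshold stayed within 1.5 times of 16 with quantile normalization (14), median centring (15), the filter on the mean (18), the mean of a gene's probe sets (15), an intensity trend with robust variance (21), a 2-fold minimum (15) and without immunoglobulin genes (12, of which 5 were higher). It was 28, with 22 higher, among genes with 3 arrays at or above the median, 27, with 16 higher, over all probe sets, 28, with 17 higher, with array quality weights, and 8, with 3 higher and 5 lower, at an adjusted p under 0.01. The filter on the mean left 13 higher and 5 lower. With a term for sex it was 29, with 23 higher, and on the Xist-low arrays 59, with 49 higher. Leaving out each array in turn gave 8 to 38 genes, 3 to 31 higher and 5 to 10 lower. Fewer genes tested, fewer samples or a stricter threshold can change a count by construction; otherwise the cause was not tested.

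With the replicate block, 0 genes passed, 0 higher and 0 lower. Sca1-MALT1 replicates 4 and 5 have no wild-type sample of their number, and the block leaves few residual degrees of freedom. The deviations of same-numbered samples correlated at -0.22, -0.04 and 0.01, and no wild-type sample correlated best with the Sca1-MALT1 sample of its own number. These values show no sign of pairing, but so few pairs cannot exclude a batch shared by number.

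Of the 35 lists, 16 passed by camera, 11 to 19 with each array left out, 0 with an estimated correlation (lowest adjusted p = 0.358) and 1 by fry's test for a shift in 1 direction. The direction of S phase genes turned without wild-type replicate 1 (adjusted p = 0.699; 0.00247 to 0.699 with each array left out). G2 and M phase genes, higher but not past the threshold over 8 arrays (adjusted p = 0.851), were lower without Sca1-MALT1 replicate 4, where they passed (adjusted p = 0.0223; 0.0223 to 0.545 with each array left out). They were also lower, not past the threshold, without wild-type replicate 2 (0.325), without Sca1-MALT1 replicate 3 (0.330), with the replicate block (0.0761), with a term for sex (0.515) and on the Xist-low arrays (0.408). The cause was not tested. Besides leaving out arrays, the filter on the mean ended the camera call of the lymphoid priming (adjusted p = 0.0854), monocyte (0.0696), interferon-induced (0.0846) and S phase (0.0791) lists, and the 3-array filter that of the stromal (0.0722), interferon-induced (0.0549) and S phase (0.0722) lists. The mean of a gene's probe sets ended that of the monocyte (0.105) and S phase (0.0969) lists, array quality weights that of the interferon-induced (0.0963) and S phase (0.114) lists, and the replicate block that of the lymphoid priming (0.0761), stromal (0.0523) and interferon-induced (0.107) lists. Apart from the turn of S phase genes without wild-type replicate 1 and that of G2 and M phase genes without Sca1-MALT1 replicate 4, the alternatives left 638 list results and 2788 gene results on their side of the threshold, took 69 and 80 from past it to short of it, and 25 and 39 the other way. The Malt1 difference stayed short of the threshold throughout. The difference in distance between and within genotypes was 0.00385 to 0.00957 with each array left out, and that in 3' minus 5' signal was -0.317 to -0.0438. Signal over background could not be judged, since RMA gives no detection call.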

Other observations

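The tests in this part were chosen after the results were seen. Immunoglobulin genes with a probe set of their own, with Jchain counted among them, were higher in Sca1-MALT1 in 19 of 21 cases. Of these, 15 had no overlap of the groups, against 0 lower without overlap. The median log2 difference was 2.66, and 2 passed the threshold, Igkv8-30 and Jchain. Of 13 kappa variable genes, 12 were higher and 9 of these had no overlap. The heavy chain gene Ighg3, of the IgG class, differed by 3.46 (SE 0.71, adjusted p = 0.204), while the heavy chain variable gene Ighv14-2 differed by -1.56 (SE 0.42, adjusted p = 0.298). Probe sets of related variable genes can read one another's transcripts, so these are not independent counts.

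The mean signal of 3 of 35 lists separated the genotypes at the smallest exact permutation p, 0.0179, where chance gives 0.625 lists. They were the plasma cell, B cell and lymphoid priming lists. Metallothionein genes Mt1 and Mt2 stood at 3.07 and 2.89, and Mt2 passed the threshold.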
